A study of Homo sapiens with 12 samples.

How the data were processed

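MDA-MB-231 cells were compared with and without 500 µM DETA/NO for 24 h by chromatin immunoprecipitation of H3K9ac and H3K9me2, with 2 biological replicates per condition and mark and 4 inputs (12 samples). Per the labels' protocols, crosslinked chromatin was sheared to 200 to 500 bp and immunoprecipitated with a Millipore antibody for H3K9ac and an Abcam antibody for H3K9me2. The submitters' processing notes name Trimmomatic 0.32, BWA 0.7.5, Picard, MACS2 and SICER and the build hg19, without saying which tool made which list. Settings, the use of the inputs and read depths are not given in the sources used here. The inputs were not analysed here.

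The deposited data were 10 interval lists without column headers. The 4 H3K9ac library lists hold peaks of single libraries with a score per peak that the authors' caller gave, from 0.3 upward. The narrowest peak was 238 and 175 bp wide in the untreated libraries and 99 and 114 bp in the treated ones. The authors also deposited 2 reproducible H3K9ac sets, 1 per condition, made from both libraries. The authors' score in these sets was read as the −log10 of an irreproducible discovery rate, deposited per region, because its lowest value of 1.301 is that of a rate of 0.05. The 4 H3K9me2 lists hold islands of single libraries on a grid of 500 bp with an authors' score of at least 5.00, and 2 islands of untreated replicate 2 have an infinite score. Other deposited columns, interval starts and ends, were used as positions; H3K9me2 ends name the last base and were extended by 1 bp. Scores are the authors' own and served only to rank intervals within a list. No list was pooled over libraries except the reproducible sets.

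Intervals were compared in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1. Regions overlapped when they shared at least 1 bp. A region was gained when it was in the treated reproducible set and met no peak in either untreated library list, and lost in the mirror case. H3K9me2 was compared in bins of 100 kb, covered when islands took at least 50% of a bin, and in bins of 1 Mb on 23 chromosomes. Similarity was the Jaccard index over covered bases. Condition means were compared by exact permutation of the labels, which has 3 splits of 4 libraries and no p below 0.333. Overlap of H3K9ac with H3K9me2 was set against 1000 circular shifts of the islands within chromosomes. Wilson intervals at 95% cover counting error only. Regions beyond the 23 chromosomes were left out of shifts and bins. The number of protein-coding genes per chromosome came from a RefSeq table on GRCh38.p14, and no coordinates were taken from it.

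The planned tests at promoters and over gene lists were not run, because they need gene positions on hg19. As set before the data were examined, merged regions took the place of promoters for H3K9ac, 100 kb bins took it for H3K9me2, and the loci named are the 10 highest-scoring gained and lost H3K9ac regions and the 10 bins of 1 Mb with the largest mean difference in each direction for H3K9me2. For merged regions the promoter count for H3K9ac reduces to that of regions gained and lost. The lists hold no signal, so limma was fitted to covered shares: limma 3.58.1 in R 4.3.3 with a mean-variance trend, on the arcsine square root of the share, leaving out features at 0 in all 4 libraries.

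The overlap code was tested on simulated intervals, where it recovered 200 of 200 gained and 100 of 100 lost regions among 5000. The limma step was tested on data simulated from the real means, with 200 features changed and the spread taken either from each feature alone or from limma's moderated estimate. This simulation was altered several times: the first version, with changes of 0.2 and 0.4 on the arcsine scale and each feature's own spread, recovered none in any data set. Larger changes, the moderated spread and larger numbers of changed H3K9ac regions were then added after those results were seen, and all versions are given here. For 1735 H3K9me2 bins of 1 Mb with each bin's own spread, changes of 0.4 were recovered in 51 and of 0.8 in 85 of 100 bins, with 9 false calls among 145. With the moderated spread these became 86 and 100 of 100, with 10 false calls among 196. When the changes were 0.2 and 0.4, 9 and 74 of 100 were recovered with the moderated spread and 0 with each bin's own. For 10583 bins of 100 kb, 16 of 100 changes of 0.8 were recovered with the moderated spread, and 0 in every other version. For 21944 H3K9ac regions, 0 of 200 and 0 of 5000 changed regions were recovered in any version. With 15000 changed by 0.2 and 0.4 it was again 0; changed by 0.4 and by 0.8, 654 and 3804 of 7500 were recovered with each region's own spread and 317 and 2216 with the moderated one. The limma step on H3K9ac thus missed simulated changes of up to 0.8 in 200 and in 5000 regions, and 0 calls in 100 kb bins carry little weight.

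Replicate numbers are shared between conditions, but no label ties a number to a batch or day. Alternatives set before the data were examined were lists cut to an equal number of peaks or to 20000, other ways to judge presence and absence, stricter scores, overlap over at least 50% of the length, islands in either library, a replicate block, quantile normalization and leaving out each library. Equal-sized reproducible sets, a width minimum of 500 bp, leaving out chromosomes M and Y, a crossed block, H3K9ac fits to regions of both sets and to bins of 100 kb, the other alternatives of the H3K9me2 fit in bins of 100 kb and a few others were added after seeing the data. The overlap between the reproducible sets, widths in shared regions, shares by score and by chromosome and the overlap of gained and lost regions with islands were likewise not set beforehand.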

Results

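The distribution of a pair of modifications of the same histone residue, lysine 9 of histone H3, was mapped by chromatin immunoprecipitation and sequencing in MDA-MB-231 cells, a human triple negative breast cancer line. Acetylation of this residue (H3K9ac) marks active promoters and enhancers, and its dimethylation (H3K9me2) marks broad silent domains. Cells were serum starved overnight and either left untreated or exposed for 24 h to 500 µM DETA/NO, a compound that releases nitric oxide slowly. There were 2 biological replicates of each condition for each mark, so 8 libraries with called intervals, and 4 input samples for which only the labels were used here. The comparison asked how nitric oxide altered where each mark lay, with the untreated cells as the control. All coordinates are on hg19, counted from 1. The lists give where a mark was called and a score, not the number of reads, so the sequencing depth behind each interval is unknown.

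H3K9ac was called in 120630 and 59724 peaks in the untreated libraries and in 79538 and 69151 peaks in the treated libraries, replicates 1 and 2 in that order. These peaks covered 48.3 and 22.8 Mb of the genome without nitric oxide and 52.1 and 37.8 Mb with it. H3K9me2 was called in 12573 and 14457 islands in the untreated libraries, covering 235.2 and 254.3 Mb, and in 14554 and 10590 islands in the treated libraries, covering 284.9 and 226.3 Mb. The median H3K9me2 island was 11500 bp ± 707 wide in untreated cells and 13750 bp ± 354 in treated cells (SD, n = 2), against 237 bp ± 4.24 and 218 bp ± 32.5 for single H3K9ac peaks. In overlap of covered bases, replicates were least alike for untreated H3K9ac. The 2 untreated H3K9ac libraries shared a Jaccard index of 0.231 over covered bases, and the 2 treated ones 0.562.

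**Figure D1:**
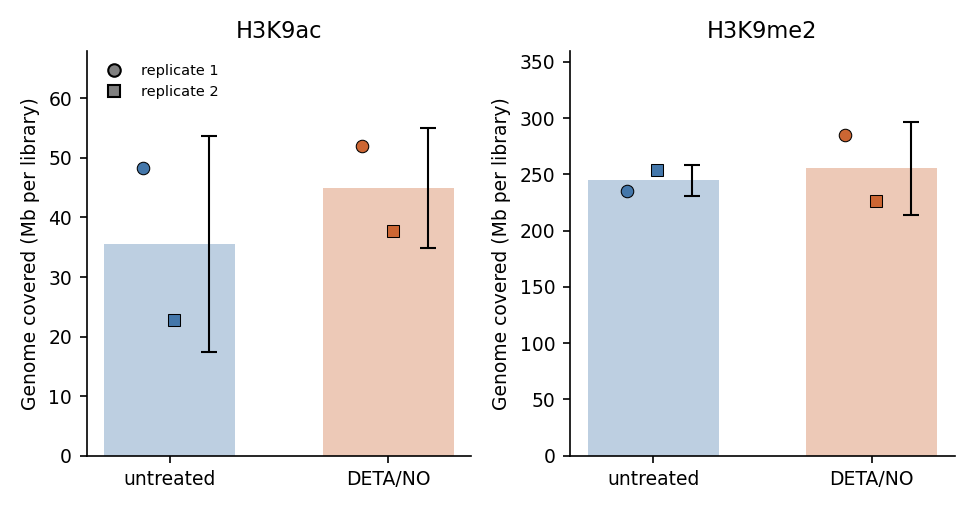
Genome length covered by called intervals in each library (Mb, vertical axis) for H3K9ac on the left and H3K9me2 on the right, untreated and DETA/NO. Points are libraries, bars are means and error bars are 1 SD (n = 2); the treated H3K9ac mean of 44.9 Mb stands above the untreated mean of 35.5 Mb with overlapping error bars, and the H3K9me2 means of 244.8 and 255.6 Mb overlap too.

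H3K9ac occupied more and wider regions in the set from treated cells. The regions that the authors kept as reproducible between replicates numbered 14377 in untreated cells, covering 17.9 Mb, and 21098 in treated cells, covering 39.3 Mb. Of the untreated regions 92.7% (95% Wilson interval 92.3 to 93.1) overlapped a treated region, whereas 54.9% (54.2 to 55.6) of the treated regions overlapped an untreated one. In the 11387 merged regions that both sets shared, H3K9ac peaks covered a mean of 1389 bp ± 222 per region in untreated cells and 2337 bp ± 288 in treated cells (SD of library means, n = 2), which was 1.68 times as much. Merging took the outer bounds of both sets, and treated regions were wider, so the choice of regions can raise this ratio. Both treated libraries lay above both untreated ones in this measure, at 2540 and 2133 bp against 1546 and 1233 bp. Every one of the 23 chromosomes counted held more reproducible regions after treatment. The ratio ran from 1.20 on chromosome 4 to 2.59 on chromosome 22. Each condition has 1 reproducible set, so the chromosomes repeat 1 difference in set size and are not separate evidence. Set size also depends on how alike the replicates were, at a Jaccard index of 0.231 untreated and 0.562 treated.

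Over whole library lists the change was smaller than the spread between replicates. Covered H3K9ac length was 35.5 Mb ± 18.1 in untreated and 44.9 Mb ± 10.1 in treated cells (SD, n = 2), a difference of 9.39 Mb with an exact two-sided permutation p of 0.667. With 2 libraries against 2 the smallest p that such a test allows is 0.333, and the difference turned to -3.40 Mb without untreated replicate 2. Lists cut to an equal number of top peaks or to the 20000 top peaks gave larger differences of 15.6 and 16.6 Mb. The mean Jaccard index of H3K9ac lists was 0.101 higher within than between conditions, against -0.036 and -0.065 for the other 2 ways of splitting the 4 libraries. The treated pair alone carried this difference: the untreated pair, at 0.231, was less alike than every pair across conditions, at 0.268 to 0.340.

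Treated cells had 3194 H3K9ac regions, 15.1% of their reproducible set (14.7 to 15.6), that met no peak in either untreated library, and untreated cells had 633, or 4.40% (4.08 to 4.75), that met none in either treated library. These are called gained and lost here. Gained regions were narrow, with a median of 598 bp against 1828 bp for the remaining treated regions, and lost regions had a median of 371 bp against 1155.5 bp. Both were weak regions: 3019 of the 3194 gained and 620 of the 633 lost regions lay in the 2 lowest of 5 equal parts of their set ranked by the authors' score. In the highest of the 5 parts, 9 of 4220 treated regions were gained and 0 of 2876 untreated regions were lost. The 175 stronger gained regions thus stood against 13 stronger lost ones. The excess of gained regions depended on how the sets were cut: with only the 14377 highest-scoring treated regions, a choice made after seeing the data, 376 were gained against 633 lost, whereas judging absence from the other of these equal-sized sets gave 3536 against 1774. Leaving out untreated replicate 1 raised the gained regions to 5872.

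**Figure D2:**
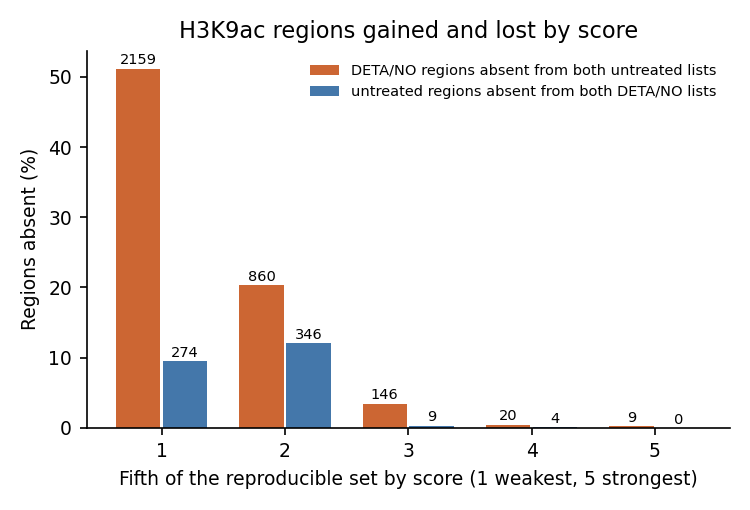
Share of H3K9ac reproducible regions (%, vertical axis) with no peak in either library of the other condition, in 5 equal parts of the set ranked by score (horizontal axis, 1 weakest). Numbers over the bars are regions; 2159 of 4220 treated regions in the weakest part were gained and 9 of 4220 in the strongest.

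The highest-scoring gained regions were short intervals, 8 of the 10 under 500 bp, and 8 of the 10 lay on chromosomes 1 and 7. Over all gained regions neither chromosome passed as over-represented by Fisher's exact test. The odds ratio was 0.971 on chromosome 1 (adjusted p = 0.794) and 1.19 on chromosome 7 (adjusted p = 0.099). A pair of them stood side by side on chromosome 1 at 1654565 to 1655002 and 1655112 to 1655312, with authors' scores of 5.72 and 5.76. Others on chromosome 1 spanned 148555224 to 148555712, 148928557 to 148928725 and 155580350 to 155580545. Chromosome 7 held 72424478 to 72424674, 74306883 to 74307676 and 102118851 to 102119027. A further gained region lay on chromosome 10 at 51622552 to 51622751. The widest of the 10 was on chromosome 6 at 37104798 to 37106370, a region of 1573 bp.

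Lost regions of the highest score were 398 to 746 bp wide. Chromosome 19 at 27735003 to 27735438 had the highest score, 3.60. Chromosome 16 held 3 of the 10, at 46389320 to 46389717, 46401665 to 46402117 and 46435315 to 46435741. From general knowledge of these chromosomes, not checked against a table here, all 4 lie near the centromere. The others were on chromosome 6 at 169241014 to 169241457, chromosome 5 at 76463836 to 76464532, chromosome 9 at 27878302 to 27879047, chromosome 11 at 48845234 to 48845767, chromosome 7 at 149473882 to 149474329 and chromosome Y at 13454324 to 13455037. Chromosome Y had 106 and 38 peaks in the untreated libraries and 2 and 48 in the treated ones, so calls there differed between replicates too. Over all untreated regions, 6 of 422 on chromosome 16 and 21 of 1142 on chromosome 19 were lost, smaller shares than on the other chromosomes together. Genes at the loci named were not assigned, since no annotation of hg19 was used here.

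By chromosome, gained regions made up a larger share of treated H3K9ac regions on chromosome 5, at 18.9% (181 of 959; odds ratio 1.32, Fisher's exact test, adjusted p = 0.0070), and a smaller share on the gene-dense chromosome 19, at 9.90% (152 of 1536; odds ratio 0.597, adjusted p = 2.2e-08). Lost regions were over-represented on 4 chromosomes, including chromosome 4 with 7.38% (45 of 610; adjusted p = 0.0040) and chromosome 7 with 7.07% (56 of 792; adjusted p = 0.0037). They were under-represented on 5, including chromosome 13 with 0 of 158 (adjusted p = 0.0070), chromosome 22 with 0 of 188 (adjusted p = 0.0039) and chromosome 15 with 1 of 289 (adjusted p = 0.00089). The others were chromosome 16 with 6 of 422 (adjusted p = 0.0065) and chromosome 19 with 21 of 1142 (adjusted p = 5.3e-05). These p-values were adjusted over 46 tests and treat regions as independent, which neighbouring regions are not.

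When presence was judged from the library lists alone, 10694 merged H3K9ac intervals lay in both treated and neither untreated library and 952 the reverse. Splitting the 4 libraries by replicate number gave 2325 and 247, and the crossed split gave 574 and 1038. In a limma fit to the covered share of 21944 merged reproducible regions, 94.8% of the regions had a higher share in treated cells. These regions were picked by calls in the same libraries, and more of them came from the treated set alone than from the untreated set alone, which by itself raises this share and the upward calls. At a Benjamini-Hochberg adjusted p under 0.05, limma called 5455 regions higher and 651 lower. In fits added after seeing the data, limma called 0 in either direction among the 11387 regions of both sets. Of these regions 98.6% had a higher share in treated cells, and 6199 had an unadjusted p under 0.05. Their median arcsine difference was 0.491, against 0.577 over all 21944 regions, so the 0 calls do not show that the difference was gone. Among 27253 bins of 100 kb that held H3K9ac peaks limma also called 0, with 4065 at an unadjusted p under 0.05. In these bins 40.3% had a higher share in treated cells, and the median arcsine difference was -0.021. The upward calls went with a shift of the distribution over the 21944 merged regions, which the bins of 100 kb did not show. After quantile normalization of those regions, which makes the distributions of the libraries equal, limma called 0 higher and 739 lower. In that fit 1614 regions had an unadjusted p under 0.05 in either direction. With the replicate number as a block limma called 16254 higher and 832 lower, and with a crossed block, added after seeing the data, 3200 and 634. Leaving out any 1 library, which leaves 1 in its condition, lowered the number called higher. Without untreated replicate 1 more regions were called lower than higher, and without either treated replicate fewer were called lower than in the main fit.

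H3K9me2 did not differ in covered length beyond the spread between replicates, and no bin of 1 Mb passed the test for change. Covered length was 244.8 Mb ± 13.5 in untreated and 255.6 Mb ± 41.5 in treated cells (SD, n = 2), a difference of 10.8 Mb with an exact two-sided permutation p of 1. Without treated replicate 1 the difference turned to -18.5 Mb. H3K9me2 lists were no more alike within than between conditions, with a mean Jaccard index 0.010 lower within conditions. The closest pair, at 0.425, was untreated replicate 1 with treated replicate 2. Islands common to all 4 libraries covered 83.7 Mb, or 17.0% of the 492.8 Mb covered in any library.

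Called islands of H3K9me2 were concentrated on a few chromosomes in all 4 libraries. Copy number was not measured here, so more calls on a chromosome need not mean more of the mark. H3K9me2 islands covered 23.5% ± 0.249 of chromosome 11, 20.2% ± 1.64 of chromosome 5, 17.3% ± 0.375 of chromosome 6 and 14.3% ± 1.61 of chromosome 20 (mean ± SD over 4 libraries, both conditions). Chromosome 22 was covered to 0.031% ± 0.0073, and chromosome 13 carried no island in any library. Of 3053 bins of 1 Mb, 27 were at least 80% covered in every library, 12 of them on chromosome 6, 7 on chromosome 11 and 2 each on chromosomes 5, 7, 8 and 18. The bin at 63000001 to 64000000 on chromosome 6 was covered to 97.6% ± 0.530 in untreated and 96.1% ± 0.354 in treated cells (SD, n = 2), and that at 97000001 to 98000000 on chromosome 11 to 95.5% ± 1.66 and 92.5% ± 1.34. Treated replicate 1 stood apart on some chromosomes, with 37.4 Mb of chromosome 4 covered against 17.5 to 24.97 Mb in the other 3 libraries, and 7.50 Mb of chromosome 2 against 2.59 to 2.71 Mb.

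**Figure D3:**
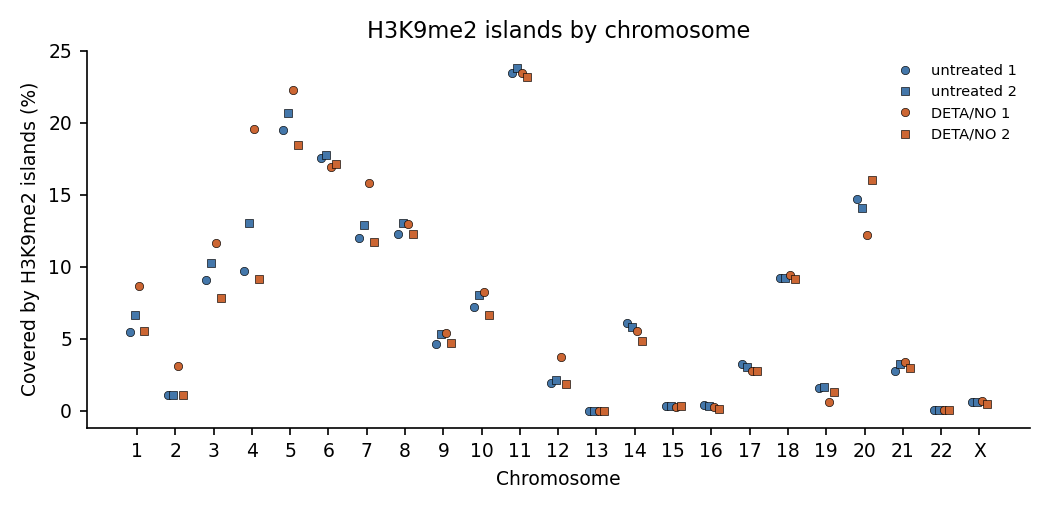
Share of each chromosome covered by H3K9me2 islands (%, vertical axis) in the 4 libraries, 1 point per library, coloured by condition. Chromosomes 11 and 5 reach 23.5% and 20.2% on average, chromosome 13 has none, and treated replicate 1 lies above the other libraries on chromosome 4.

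Single megabases of H3K9me2 that differed most between conditions lay on chromosomes 3, 4, 6, 7, 11 and 12. The largest positive difference in mean coverage was on chromosome 7 at 133000001 to 134000000, from 18.2% ± 0.141 to 57.1% ± 1.20 (SD, n = 2; limma, adjusted p = 0.947). Nearby, 141000001 to 142000000 on the same chromosome had 31.1% ± 2.62 in untreated and 49.4% ± 1.27 in treated cells. Chromosome 4 had 4 of the 10 bins with the largest positive difference; at 156000001 to 157000000 coverage was 11.6% ± 3.43 and 32.3% ± 6.19, and at 100000001 to 101000000 it was 5.98% ± 0.177 and 22.6% ± 12.1. The largest negative differences were on chromosome 6, where 21000001 to 22000000 had 60.8% ± 5.62 in untreated and 28.9% ± 22.0 in treated cells, and 40000001 to 41000000 had 92.3% ± 0.742 and 73.4% ± 1.63. The last of these turned direction when only the higher-scoring part of each list's islands was kept, with a difference of 18.03 percentage points, and the differences at 133000001 on chromosome 7 and 156000001 on chromosome 4 fell from 38.9 to 26.8 and from 20.65 to 10.3 points. In 6 of the 10 bins with positive and 5 of the 10 with negative differences, the 2 treated replicates lay further apart than the condition means.

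Across 1735 bins of 1 Mb that carried islands, limma called 0 higher and 0 lower at an adjusted p under 0.05, and 48 bins had an unadjusted p under 0.05. The same fit to 10583 bins of 100 kb called 0 as well, with 313 at an unadjusted p under 0.05. In settings added after seeing the data, limma called 1524 bins of 100 kb higher and 86 lower without treated replicate 2, and 5 higher and 14 lower with the replicate number as a block. By presence alone, 61 bins of 100 kb were at least 50% covered in both treated and neither untreated library, and 75 the reverse, beside 73 and 62 for the split by replicate number and 150 and 94 for the crossed split. These counts rested on having all libraries: leaving out untreated replicate 1 or 2, or treated replicate 1 or 2, gave 113, 121, 261 and 647 gained bins and 301, 266, 148 and 219 lost ones.

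**Figure D4:**
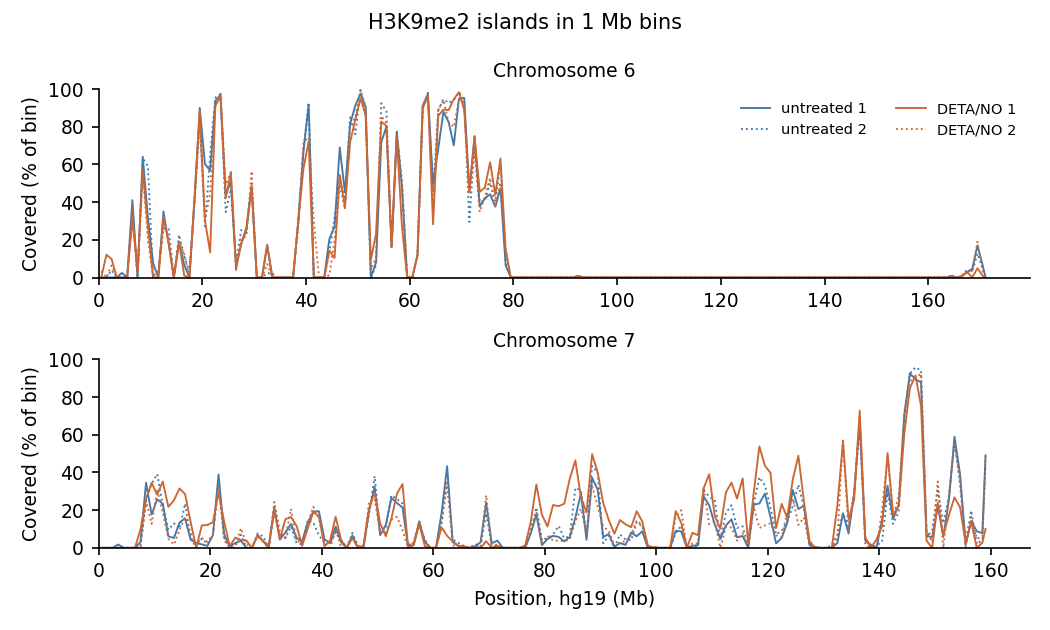
Share of each 1 Mb bin covered by H3K9me2 islands (%, vertical axis) along chromosomes 6 and 7 (hg19 position in Mb, horizontal axis), 1 line per library, solid for replicate 1 and dotted for replicate 2. Islands fill much of chromosome 6 up to 78 Mb and cover 0.139% of 78 to 160 Mb on average over the 4 libraries; from 133000001 to 134000000 on chromosome 7 both treated lines rise above both untreated lines.

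The series placed both marks on the same residue side by side, and the called regions of one were nearly excluded from those of the other. In untreated cells 47 of 14351 H3K9ac reproducible regions, 0.328%, overlapped H3K9me2 islands found in both libraries, against a mean of 5.35% (central 95% of shifts 4.08 to 6.89) when the islands were shifted along their chromosomes. In treated cells it was 6 of 21096, 0.028%, against 4.48% (3.53 to 5.70). The two-sided permutation p was 0.0020 for each, the smallest that 1000 shifts can give. Of the 3193 gained regions on the shifted chromosomes, 0 overlapped treated islands, where shifted islands gave 4.52%. The gained and lost regions were tested in this way only after seeing the data. Of 626 lost regions, 40 overlapped untreated islands, 6.39% (95% Wilson interval 4.73 to 8.58), against 6.31% for shifted islands (permutation p = 0.967) and against 7 of 13725 of the other untreated regions (Fisher's exact test, odds ratio 133.8, p = 5.4e-48). Regions on the same chromosome are not independent, so the Fisher value overstates the evidence.

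**Figure D5:**
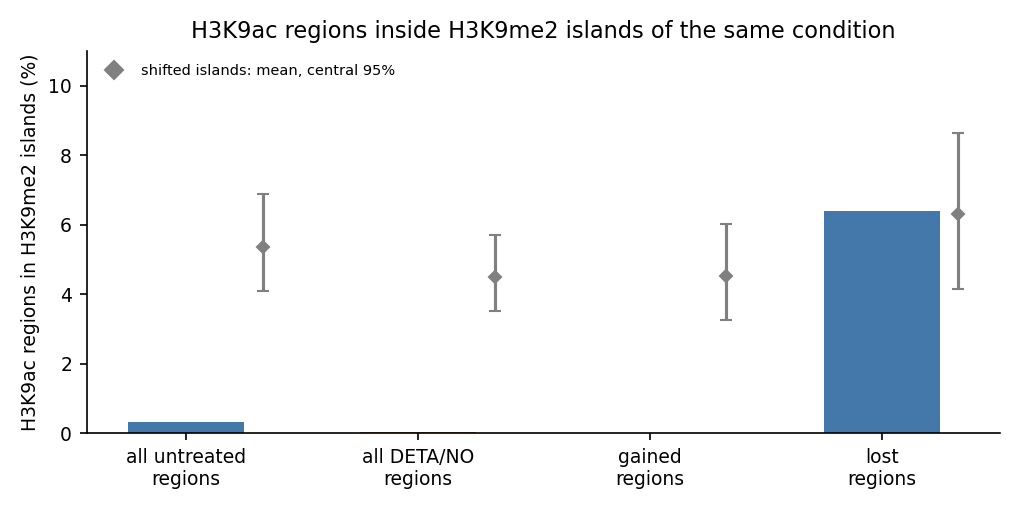
Share of H3K9ac regions (%, vertical axis) that overlap H3K9me2 islands present in both libraries of the same condition, for all regions of each condition and for gained and lost regions. Bars are observed shares, and grey diamonds with bars give the mean and central 95% of 1000 shifts; only the lost regions, at 6.39%, lie within their shifted range.

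Opposite changes of the marks in the same place were not detected, but few bins had gained or lost H3K9me2, so the test had little power. Its p-values were adjusted over the opposite pairs together with the pairs in which both marks were gained or both lost. Of 219 bins of 100 kb that held H3K9ac regions and were at least 50% covered by H3K9me2 in some library, 22 held a gained H3K9ac region and 5 had lost H3K9me2, with 1 in common against 0.502 by chance (odds ratio 2.30, Fisher's exact test, adjusted p = 0.805). Lost H3K9ac regions lay in 80 of these bins and gained H3K9me2 in 10, with 2 in common against 3.65 by chance (odds ratio 0.420, adjusted p = 0.805). Counting bins with at least 1 bp of H3K9me2, a choice made after seeing the data, gave 1801 bins, in which H3K9ac lost and H3K9me2 gained met in 5 against 12.2 by chance (odds ratio 0.356, Fisher's exact test, p = 0.017, adjusted p = 0.067), and H3K9ac gained and H3K9me2 lost in 8 against 7.25 (odds ratio 1.13, adjusted p = 0.916).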

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

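Of 156 recomputed values, 80 belong to alternatives chosen after seeing the data. Among them were equal-sized sets, the width minimum, the crossed block, the settings tried in bins of 100 kb and every gained minus lost difference. Of all 156, 93 stayed within a set margin of the reported value or, for covered lengths and tests, kept its direction or outcome. A further 4 turned direction. The rest moved by more than the margin, 56 among the main results and 3 among the named H3K9me2 bins. For a named bin the margin was the larger SD of its 2 conditions, which can be wide. With only the higher-scoring islands, the bin at 41000001 on chromosome 6 fell from 14.7 to 0 points within that margin. The bin at 9000001 on chromosome 6 went from -22.1 to -4.3 points, also within it. Cutting the lists to 20000 peaks gave 6659 H3K9ac regions gained and 1003 lost, a difference of 5656, and a similarity difference of 0.174. Judging absence from the other reproducible set alone gave 9512, 1046 and 8466, and presence in both library lists gave 10694, 952 and 9742. The higher-scoring part of each reproducible set left 65, 7 and 58. Overlap over at least 50% of the length gave 9346 gained, a difference of 8475, and set overlaps of 92.2% and 39.4%. A width of at least 500 bp left 1977 gained and 105 lost. Equal-sized reproducible sets gave 376 gained, a difference of -257, and set overlaps of 87.7% of untreated and 75.4% of treated regions, while judging absence from the other of these sets gave 3536 gained and 1774 lost. The turn to -257 follows from removing the weakest treated regions, where most gained regions lie. For the other changes the cause was not tested.

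Leaving out 1 library gave 3954 to 5872 gained H3K9ac regions, a gained minus lost difference of 2406 to 5239, covered length differences of -3.40 to 22.2 Mb for H3K9ac (turning without untreated replicate 2) and -18.5 to 40.1 Mb for H3K9me2 (turning without treated replicate 1), 113 to 647 gained and 148 to 301 lost H3K9me2 bins, and 273 to 3229 higher and 18 to 799 lower H3K9ac regions by limma. Where a condition kept 1 library, limma assumed that it varied like the other condition. H3K9me2 bins of 100 kb covered by at least 1 bp gave 270 gained and 260 lost, and the higher-scoring islands 33 and 44. That setting also turned the bin at 40000001 to 41000000 of chromosome 6 to a difference of 18.03 percentage points. Quantile normalization took the H3K9ac regions called higher by limma from 5455 to 0 (1614 regions at an unadjusted p under 0.05). Fits added after seeing the data, to regions of both sets and to bins of 100 kb, called 0 higher and 0 lower for H3K9ac. In these limma fits 6199 of 11387 regions and 4065 of 27253 bins had an unadjusted p under 0.05. The median arcsine difference was 0.491 in regions of both sets, against 0.577 in the main fit. Limma called 0 H3K9me2 bins of 1 Mb in all settings run, with 17 to 342 at an unadjusted p under 0.05. Bins of 100 kb went from 0 to 1524 higher and 86 lower without treated replicate 2, to 5 and 14 with the replicate block and to 11 and 17 with no bin left out, and gave 0 in the other settings run.

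With the replicate number as a block, limma called 16254 H3K9ac regions higher; covered length differed by 9.39 Mb for H3K9ac (exact p = 0.5) and 10.8 Mb for H3K9me2 (exact p = 1). Deviations of same-numbered libraries correlated at -0.113 over H3K9ac regions and -0.394 over H3K9me2 bins of 1 Mb, so a crossed replicate block was added, with which limma called 3200 H3K9ac regions higher and 634 lower and 0 H3K9me2 bins. Promoter windows of 1 or 2 kb, single 5′ ends, gene bodies and gene lists with either background were not run, as gene positions on hg19 were not used here. Reproducible sets could not be remade with a library left out. Depth is unknown, so what the untreated lists could not detect cannot be told from what was absent.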

Other observations

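The counts of gained and lost regions were planned; the tests set against them, the overlap of gained and lost regions with islands, the relations over chromosomes and the other tests in this part were chosen after seeing the data, and the bounds for gained regions in the weakest parts and for weak peaks were set again once their values were known. Regions with H3K9ac followed gene number across chromosomes. Over 23 chromosomes, reproducible regions per Mb correlated with protein-coding genes per Mb at r = 0.956 and rho = 0.758 in untreated cells (permutation p = 1e-05 and 1e-04) and at r = 0.986 and rho = 0.924 in treated cells (permutation p = 1e-05 for both, the smallest that 100000 resamples give). Without chromosomes 17 and 19, the farthest in gene density, r was 0.729 and 0.924. The adjusted p over 7 relations was at most 0.00035 for these. Chromosome 22 carried 0.417 regions per gene in untreated and 1.08 in treated cells, and chromosome 13 carried 0.467 and 1.04.

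Called H3K9me2 islands ended abruptly along 2 chromosomes. On chromosome 6, islands covered 40.6% ± 0.960 of 6 to 78 Mb and 0.139% ± 0.050 of 78 to 160 Mb (mean ± SD, n = 4 libraries of both conditions). On chromosome 8 they covered 0.045% ± 0.016 of 0 to 81 Mb and 30.9% ± 1.09 of 81 to 140 Mb. In the nearly empty parts, treated cells had 2.26 and 2.32 times as many reproducible H3K9ac regions as untreated cells, against 1.31 and 1.298 times in the covered parts. These bounds were set by eye.

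Gained H3K9ac regions outnumbered lost ones by 3194 to 633. Treated lists that reach weaker regions and a wider acetylated territory in treated cells are both open. By score the treated library lists reached no lower, since the lowest score was 0.31 or 0.30 in every list. Median scores were 1.72 and 1.48 in untreated and 3.22 and 2.65 in treated libraries, but scores of different lists may not be comparable. The size of a reproducible set also depends on how alike its libraries were, at a Jaccard index of 0.231 untreated and 0.562 treated. What part this played was not tested. Of the gained regions 94.5% lay in the 2 weakest of 5 equal parts of their set, but so did 97.9% of the lost ones, so weakness does not set the gained regions apart. Equal-sized sets did not separate the explanations either: the difference was -257 with absence judged from the library lists and 1762 with absence judged from the other set. Stronger enrichment and more acetylation cannot be told apart here, because the lists hold no read counts.

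Lost H3K9ac regions overlapped untreated H3K9me2 islands 1.01 times as often as shifted islands did, whereas gained regions did not overlap them. A candidate explanation is that many lost regions were background calls, since a background call would take no account of H3K9me2; 7 of the 13725 other untreated regions overlapped these islands. H3K9me2 taking the place of lost acetylation was not seen at most lost regions. Of these, 14.4% met treated islands of either library, with an upper bound of 17.3%, where shifted islands gave a mean of 16.3%. In islands found in both libraries, 8 regions met only treated and 14 only untreated ones, which decides nothing (exact binomial test, p = 0.286). Replacement at a smaller part of the regions cannot be excluded, since the treated island lists shared a Jaccard index of only 0.336. Loss of true acetylation at a part of these regions stays open.

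H3K9me2 crowded on some chromosomes, and its coverage did not clearly follow gene density. Over 23 chromosomes coverage correlated with genes per Mb at rho = -0.114 (r = -0.184, permutation p = 0.604 and 0.416). So few chromosomes cannot exclude a moderate relation, and gene density within chromosomes was not tested. A change of H3K9me2 with treatment did not follow the ratio of treated to untreated H3K9ac regions either (rho = 0.050, r = -0.169, permutation p = 0.820 and 0.435). Coverage itself did, at rho = -0.650 and r = -0.594 (permutation p = 0.0010 and 0.0028, adjusted p = 0.0028 and 0.0065 over 7 relations; r = -0.546 without chromosomes 5 and 11), and within chromosomes the untreated to treated ratio followed it at rho = 0.132 over 1823 bins (permutation p = 0.0020, the smallest 1000 shifts give). Segments present in more copies, which this aneuploid line may carry, could give more reads and more calls of both marks: weak H3K9ac peaks per 1 Mb bin followed H3K9me2 coverage at a given number of strong peaks in all 4 libraries, with a lowest partial rho of 0.283, where shifted islands gave a mean of 0.148 in that library (permutation p = 0.0020), and 0.400 to 0.589 in the others, where they gave 0.156 to 0.292. Copy number was not measured here, so true domains of H3K9me2 stay open beside it.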
